A study of Caligus rogercresseyi with 6 samples.

How the data were processed

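RNA-seq was carried out on whole animals of Caligus rogercresseyi, a parasitic copepod (sea louse) of farmed salmon. The labels describe 6 samples, each RNA from pooled animals, in 6 groups of 1: eggs, copepodids (the free-swimming infective larva), chalimi (the larva attached to the host), adult females, adult males and adults with no sex given. Per the labels' protocols, tissue was homogenised in a mixer mill in Trizol, cleaned on RNeasy columns and made into libraries by standard Illumina procedures. The aligner, the counting tool and the assembly method are not given in the sources used here.

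Each deposited file lists the same 44089 transcript contigs by GenBank identifier, with a whole-number count and an FPKM. How reads matching several contigs were counted is not given. If the whole numbers are rounded output of a tool that divides such reads, the exact intervals and the bounds for 0 counts below are approximate. The counts as deposited by the authors are not normalised, per the file headers and the values, and their totals differ between files. The FPKM values deposited by the authors are scaled by contig length and library total, and were rounded to 3 decimals. Dividing counts by FPKM gave whole-number contig lengths within 0.05 nt for 100% of the contigs with FPKM above 300 in every file. Lengths (200 to 20017 nt, median 940 nt, 38731 contigs) were therefore recovered from the counts and the FPKM. That check covered only 279 to 454 contigs per file. For contigs with very low FPKM in every file, the rounding makes the recovered length approximate. The same division gave the total that the FPKM were scaled by. Every ratio below rests on the counts.

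No file pairs the identifiers with gene names, no sequence was used here, and the 17 gene lists fixed beforehand by name (cuticle, yolk, peptidases, muscle, germ line, host tissue and others) therefore could not be applied to any contig. Contigs are reported by identifier, and no gene function is given for them.

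The deposited totals were 120674263 counts for egg, 78380827 for copepodid, 116318842 for chalimus, 149426248 for adult female, 130218357 for adult male and 279644605 for the adult sample of unstated sex. The last total equals the sum of the female and male totals exactly, with a difference of 0 counts. Of the 20418 contigs with 100 or more counts in that sum, 43.5% held exactly the sum, against 1.31% in a Poisson simulation of a separate library. The adult file of unstated sex was therefore treated as the female and male data counted again, and 5 libraries were taken as independent. Its comparison with chalimus was kept as planned but carries no evidence beyond the other two.

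Counts were scaled with trimmed mean of M-values (TMM) factors over the 6 files (edgeR 4.0.16, R 4.3.3). Log2 ratios were computed after adding 0.5 counts per library, scaled to its size. With 1 library per group no test was possible, so no p-values or standard errors are given and every difference lacks a replicate check. A rule of size was used instead, fixed with the groups, comparisons and alternatives before the data were examined: a contig counted as higher or lower when it differed at least 4-fold and had at least 50 counts in the higher library. Ratios of 2 counts carry a 95% exact (Clopper-Pearson) interval, and a fold against 0 counts is a lower bound computed with 3 counts in the empty library, the 95% one-sided limit, and printed as the lowest value among TMM, total-count and DESeq2 scaling. Other folds are TMM-scaled, whereas CPM are counts over the library total, so ratios of 2 printed CPM differ from the folds, most of all for copepodid. Bounds against 0 counts in copepodid assume that none of the counts absent from its table belong to the contig. These intervals and bounds cover counting error only, since the reads carry no molecular identifiers, and the spread between pools of animals is unknown. A share of counts has a Wilson 95% interval of at most 0.0111 percentage points on either side, even in the shallowest library. A count of 0 allows up to 3 counts, between 0.0201 CPM in adult female and 0.0383 CPM in copepodid among the 5 independent libraries.

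On simulated data with 200 changed contigs, run on all 44089 contigs, the size rule called 100% of the 8-fold changes and 0% of the 2-fold changes for both copepodid versus egg and adult female versus adult male. It called 0 unchanged contigs in each. The changed contigs came from those with at least 50 expected counts in both libraries, the noise was Poisson and the scaling was known. A 4-fold cut then separates 2-fold from 8-fold almost by construction. The simulation checks the computation, and does not show how often real pools would pass the rule without a difference. The counting intervals covered the true ratio for 95.5% and 95.3% of the contigs with at least 50 expected counts in both libraries.

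The 2 contigs with the largest and the 2 with the smallest ratio per comparison were named, among those with at least 200 counts in the higher library, plus the most abundant contig of each library. Alternatives were scaling by total counts (CPM), DESeq2 1.42.0 size factors, minimums of 10 counts and of 0 counts, 3 added counts, thinning to the shallowest library, intervals wholly beyond 4-fold, and leaving the most abundant contigs out of the scaling. Summing contigs of one gene was planned only where identifiers show it, and they do not. Leaving out contigs counted in the copepodid library alone, scaling without the adult file of unstated sex, and comparing chalimus directly with egg were added after seeing the data, as were the cross-tabulations of sex-biased contigs with stage. Correlations between libraries are across contigs, which are not independent replicates. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

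The count of a contig depended on which reads were counted together. Between the adult file of unstated sex and the sum of the sexes, 12337 contigs moved by 5 or more counts while the total stayed the same, and in 2058 pairs of consecutive identifiers 1 contig gained what the other lost, against 47 such pairs when the shifts were shuffled among contigs. In all, 0.277% of the counts moved. Similarity between contigs was not measured, since no sequence was used, so values of contigs that share reads with another are uncertain.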

Results

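Transcript abundance was measured by RNA-seq in whole-animal pools from selected life stages of the sea louse Caligus rogercresseyi. These were eggs, copepodids, chalimi, adult females and adult males, each as 1 library. Totals of the 5 independent libraries ranged from 78380827 counts in copepodid to 149426248 in adult female. A sixth file, labelled adult with no sex, held the female and male data counted together. Of the 44089 contigs in the files, 38733 had at least 1 count and 5356 had none. In the 5 independent libraries, between 24312 contigs (adult female) and 26447 contigs (copepodid) had 10 or more counts.

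The libraries differed in how far a few contigs dominated them. In chalimus the 10 most abundant contigs held 8.37% of the counts, in adult male 10.3%, in egg 11.6%, in adult female 16.3% and in copepodid 25.7%. Most abundant means, throughout, holding the most counts, with no correction for contig length, which favours long contigs. By this ranking contig GAZX01041366 (6139 nt) was the most abundant in egg, at 25213 CPM, and in adult male, at 12410 CPM. The far shorter GAZX01006047 (635 nt) was close behind it in adult male, at 11985 CPM, so a ranking per nt would differ. Contig GAZX01041365 (2576 nt), the next identifier, led the copepodid library at 69000 CPM. Contig GAZX01030310 (2990 nt) led chalimus at 16668 CPM and stayed between 8918 and 16668 CPM in all 5 independent libraries. Contig GAZX01008936 (5872 nt) led adult female at 43896 CPM, which was 4.39% of that library.

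Rank correlations across contigs placed chalimus nearest to the adults. Spearman's rho was 0.88 between chalimus and adult male, 0.81 between chalimus and adult female, 0.79 between egg and adult female, 0.78 between egg and chalimus, 0.77 between the sexes and 0.71 between egg and adult male. The copepodid library stood apart, with rho between 0.33 (adult female) and 0.43 (egg). Without the contigs counted in the copepodid library alone, its rho rose to between 0.58 and 0.73. The 0.73, with egg, was then above the 0.71 between egg and adult male. With at least 50 counts in each library of a pair, copepodid had a rho of 0.71 with egg and 0.71 with chalimus. At that setting egg and adult male had 0.69, so for shared contigs copepodid stood apart from the adults more than from egg and chalimus.

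**Figure D1:**
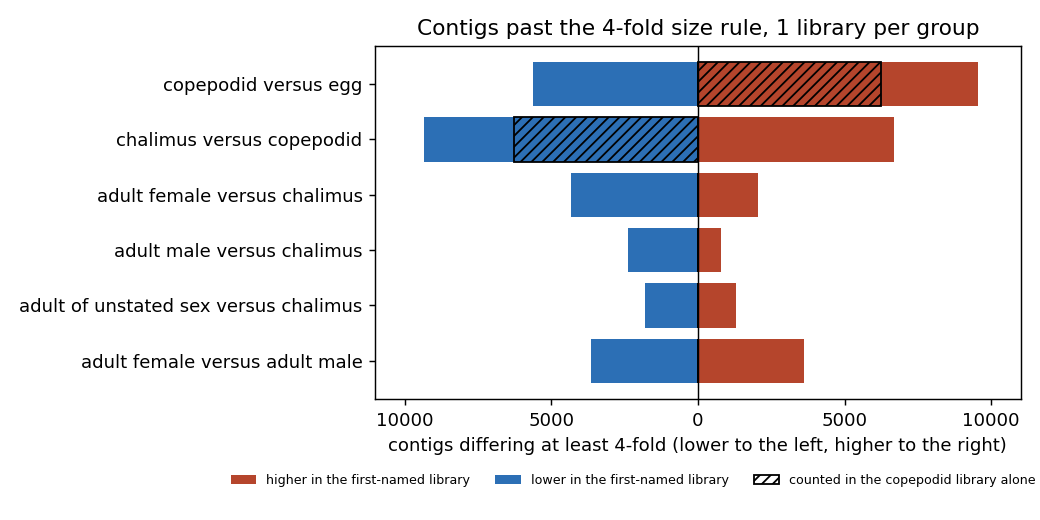
Number of contigs differing at least 4-fold in each comparison (horizontal axis, contigs; right, higher in the first-named library; left, lower), 1 library per group. Hatching marks contigs counted in the copepodid library alone, which make up 6260 of the 9548 contigs higher in copepodid than in egg.

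Copepodid, a free-swimming larva, was compared with egg, the only earlier stage sampled. Among 28633 contigs with at least 50 counts in either library, 9548 (33.3%) were higher and 5633 (19.7%) were lower in copepodid. The contigs higher in copepodid took 47.9% of the copepodid counts and 10.2% of the egg counts. The contigs lower in copepodid took 10.3% of the egg counts and 0.475% of the copepodid counts. The most abundant contig of the copepodid library, GAZX01041365, was 8.50-fold higher there than in egg (95% counting interval 8.49 to 8.52), and GAZX01041366 was 4.84-fold higher (4.83 to 4.84), both with TMM scaling. With total counts they were 4.33-fold and 2.46-fold higher, so the second passed the 4-fold rule with TMM but not with total counts.

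Most contigs higher in copepodid belonged to a set counted in no other library here, and stages outside the labels were not sampled. Of the 9548, 6260 had 0 counts in egg, chalimus, adult female and adult male. Those 6260 contigs were short, with a median length of 304.5 nt and a 5th to 95th percentile of 210 to 644 nt, whereas the 16667 other contigs with 50 or more copepodid counts had a median of 1539 nt. All 7055 contigs counted in copepodid alone, including those under 50 counts, held 4.46% of the library. The named examples were GAZX01017135 (397 nt, 461 CPM, at least 18554-fold higher than in egg) and GAZX01027244 (893 nt, 395 CPM, at least 15871-fold). Leaving out the contigs of copepodid alone turned the balance, with 3278 contigs higher and 5652 lower in copepodid than in egg.

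Conversely, some contigs that the other 4 independent libraries shared had 0 counts in the copepodid table. There were 687 contigs with 0 counts in copepodid and at least 100 counts in each of the other 4 independent libraries, with a median length of 1318 nt, whereas the corresponding number was at most 4 for any other library. Only 61 contigs with at least 100 counts in each of the others had 1 count in copepodid. Of the total behind the copepodid FPKM, 1.08% is not in the table and cannot be assigned to contigs, so 0 counts in copepodid means 0 in the table, and every bound against it, here and below, holds only if no counts of that contig were left out. The 2 contigs named for the lowest ratio to egg were not among the 687. Contig GAZX01013662 (1379 nt) had 24172 counts in egg and 20175 in adult female, 2 in adult male and 0 in copepodid and chalimus. It was at least 2382-fold lower in copepodid than in egg. Contig GAZX01014791 (989 nt) was also lower, at 143 CPM in egg, 34.3 CPM in adult female, 38 counts in chalimus, 2 in adult male and 0 in copepodid (at least 1703-fold lower). The balance of this comparison also depended on scaling. With TMM 62.9% of the differing contigs were higher in copepodid, with total counts 50.1% and with DESeq2 size factors 64.7%; the median log2 ratio of all contigs was 0.28, -0.69 and 0.45 respectively.

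**Figure D2:**
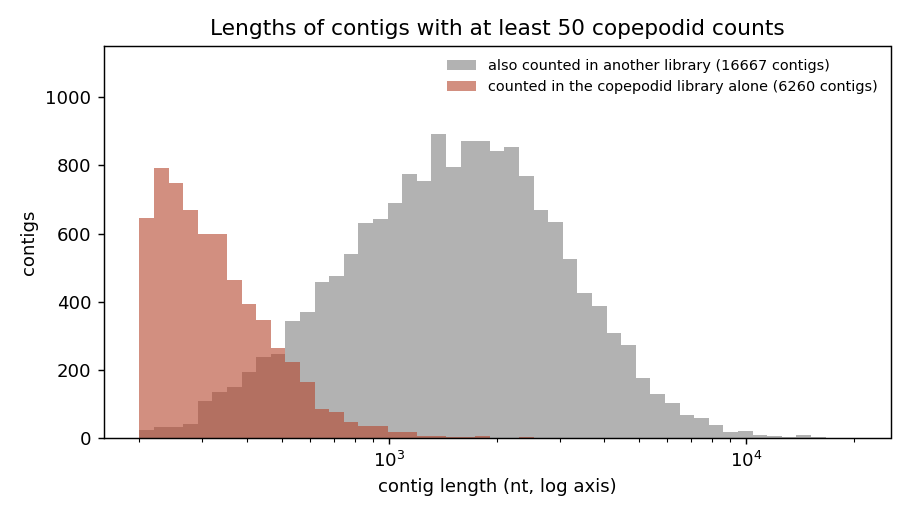
Lengths (nt, log axis) of contigs with at least 50 counts in the copepodid library, split into the 6260 counted in no other independent library and the 16667 also counted elsewhere; bars are numbers of contigs. The first set has a median of 304.5 nt and the second of 1539 nt.

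Settlement on the host separates the copepodid from the chalimus. Among 29177 contigs, 6684 (22.9%) were higher and 9327 (32.0%) were lower in chalimus than in copepodid, and 6260 of the lower ones were the contigs of copepodid alone. Without the contigs of copepodid alone the balance turned, to 6729 higher and 3036 lower in chalimus. The higher contigs held 22.0% of the chalimus counts and 1.07% of the copepodid counts. Contig GAZX01006047 (635 nt) had 0 counts in copepodid and 2646 CPM in chalimus (at least 40321-fold higher, if none of its copepodid counts were left out of the table), and reached 7399 CPM in adult female and 11985 CPM in adult male. Contig GAZX01012036 (1325 nt) followed the same course, at 0 counts in copepodid, 849 CPM in chalimus, 950 CPM in adult female and 1652 CPM in adult male. In egg these contigs had 71 and 2 counts.

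Among the contigs lower in chalimus, GAZX01021855 (888 nt) had 706 CPM in copepodid and 371 CPM in egg but 0 counts in chalimus, and 3.19 CPM in adult female. It was at least 27390-fold lower in chalimus than in copepodid. The most abundant copepodid contigs were lower in chalimus as well. GAZX01041365 stood in chalimus at 0.0982 of its copepodid level (interval 0.0980 to 0.0983), and GAZX01041366 at 0.119 of it, with TMM scaling, and at 0.163 and 0.197 with total counts. When chalimus was set against egg directly, without the copepodid library, 3925 contigs were higher and 2380 lower in chalimus. The median log2 ratio of all contigs in chalimus against copepodid was -0.23 with TMM, 0.50 with total counts and -0.28 with DESeq2 size factors, and 41.7%, 49.96% and 41.2% of the differing contigs were higher in chalimus.

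Females and males were each compared with chalimus to describe the final moults. In adult female 2059 contigs were higher and 4323 lower than in chalimus, among 22402. In adult male 783 were higher and 2394 lower, among 22033. The contigs higher in adult female held 25.7% of the female counts and 2.91% of the chalimus counts, and the contigs higher in adult male held 11.7% of the male counts and 2.05% of the chalimus counts. GAZX01008936 was 11.3-fold higher in adult female than in chalimus (11.26 to 11.32), where it already stood at 3985 CPM, and in adult male it was at 34.6 CPM.

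Examples of contigs higher in adult female were GAZX01013662, at 135 CPM against 0 counts in chalimus, and GAZX01001968 (917 nt), at 7.92 CPM against 0 counts (at least 307-fold). Both had higher levels in egg, 200.3 and 153 CPM. In adult male, GAZX01034905 (621 nt) reached 690 CPM (89915 counts) against 93 counts in chalimus, a 980-fold difference (interval 800 to 1214), with 1.41 CPM in adult female. GAZX01031953 (2271 nt) was 285-fold higher in adult male than in chalimus (111 to 1048) and had similar levels in both sexes, 8.64 and 6.92 CPM. Its chalimus level was only 4 counts, and on pooled recounting of the sexes its count changed by -89. The assignment of reads thus makes this fold less certain than its counting interval.

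Contigs lower in the adults included several abundant in chalimus. GAZX01016488 (819 nt) had 3126 CPM in chalimus and 716 CPM in copepodid, against 5 counts in adult female and 79 in adult male. It was 91157-fold lower in adult female than in chalimus (39061 to 280746). On pooled recounting of the sexes it gained 14 counts, more than the 5 in adult female. The assignment of reads thus makes this fold less certain than its counting interval. GAZX01031616 (705 nt) had 722 CPM in chalimus, 43.1 CPM in copepodid, 1 count in adult female and 7 in adult male. The female ratio was 105290-fold with an interval of 18897 to 4158780. On pooled recounting this contig gained 1 count, as many as in adult female, so its fold is uncertain in the same way. GAZX01037499 (1013 nt, 161 CPM) and GAZX01023015 (965 nt, 108 CPM) had 0 counts in adult male, at least 5454-fold and 3671-fold lower, and 56 and 8 counts in adult female. The 56 counts are uncertain, since on pooled recounting GAZX01037499 had 38.

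The sexes shared more contigs that were lower than contigs that were higher. In both sexes 1338 contigs were lower than in chalimus, where independent lists would share 451, and 99 were higher, where they would share 70.3. Simulated unchanged libraries with counting noise alone shared 0 in each direction. The 4-fold rule with at least 50 counts almost fixes that outcome in advance, so it adds no support. That simulation also holds no variation between pools of animals. Both comparisons use the same chalimus library, which cannot be split, so part or all of the excess can come from that library. The 1338 contigs held 10.6% of the chalimus counts, 6.05% of the copepodid counts and 1.80% of the egg counts, but 0.0931% of the female and 0.294% of the male counts. In the adult file of unstated sex, 1289 contigs were higher and 1817 lower than in chalimus. Requiring all 3 adult files to pass left 98 higher and 1334 lower, and this file adds no independent evidence.

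Scaling also moved the male comparison. The median log2 ratio of all contigs in adult male against chalimus was -0.14 with TMM, -0.33 with total counts and 0.03 with DESeq2 size factors. Of the differing contigs 24.6%, 18.8% and 31.1% respectively were higher in adult male.

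**Figure D3:**
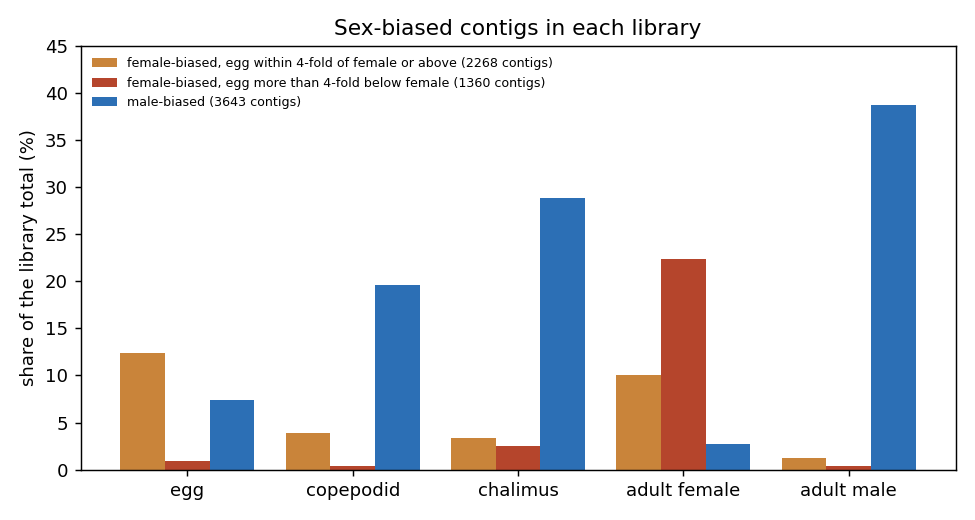
Share of each library's counts (vertical axis, percent) held by 3 classes of sex-biased contigs in the 5 independent libraries. Contigs higher in female than in male and low in egg hold 22.4% of the female library and 0.883% of the egg library, and contigs higher in male hold 38.8% of the male and 28.8% of the chalimus library.

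Adult female and adult male were compared for sex-biased transcripts. Nearly equal numbers were biased each way: 3628 contigs (16.8% of 21543) were higher in female and 3643 (16.9%) were higher in male. Female-biased contigs made up 49.9% of the differing contigs with TMM, 55.0% with total counts and 45.1% with DESeq2 size factors, with a median log2 ratio of all contigs of 0.02, 0.16 and -0.13, so the larger side depends on the scaling. Female-biased contigs held 32.5% of the female counts and 1.67% of the male counts, and male-biased contigs held 38.8% of the male and 2.70% of the female counts. The female share was concentrated, since the 10 most abundant female-biased contigs held 14.1% of the female library, against 7.35% of the male library for the 10 most abundant male-biased contigs. GAZX01008936 was 1146-fold higher in female (1113 to 1181). GAZX01026756 (1777 nt, 793 CPM) and GAZX01020589 (1186 nt, 495 CPM) had 0 counts in male, at least 28052-fold and 17513-fold lower than in female. GAZX01002694 (673 nt, 308 CPM) and GAZX01002695 (429 nt, 190 CPM), consecutive identifiers, had 0 counts in female, at least 15332-fold and 9484-fold lower than in male.

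Female-biased contigs split by their level in eggs. In 2268 of them the egg level was within 4-fold of the female level or above it, and this group held 10.1% of the female and 12.4% of the egg counts, against 3.33% in chalimus and 1.28% in adult male. The other 1360 were more than 4-fold lower in egg than in female. They held 22.4% of the female counts, 0.883% of the egg counts, 0.362% of the copepodid counts, 2.56% of the chalimus counts and 0.389% of the male counts, and GAZX01008936, GAZX01026756 and GAZX01020589 were among them.

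Male-biased contigs were also counted before adulthood, nearest to the male level in chalimus. They held 28.8% of the chalimus counts, 19.6% of the copepodid counts and 7.41% of the egg counts. Over all contigs, too, adult male was nearest to chalimus among the independent libraries (rho 0.88). Between these libraries 18856 of 22033 contigs were neither higher nor lower by the 4-fold rule. Nearness in chalimus was therefore not particular to male-biased contigs. Relative to adult male the median log2 ratio of the 3643 contigs was -0.72 in chalimus, -2.08 in copepodid and -2.37 in egg, and 523 of them were at least 4-fold lower than in male in chalimus, 1853 in copepodid and 2028 in egg. For the 3628 female-biased contigs the median log2 ratio to adult female was -1.99 in chalimus, -3.10 in copepodid and -1.47 in egg, and 1793 were at least 4-fold lower in chalimus. GAZX01002694 and GAZX01002695 had 68.2 and 61.4 CPM in chalimus and 0 counts in egg and copepodid, and the first was among the 523. Among the 12983 contigs with a change of at most 1% on pooled recounting, 17.7% were female-biased and 16.6% male-biased.

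**Figure D4:**
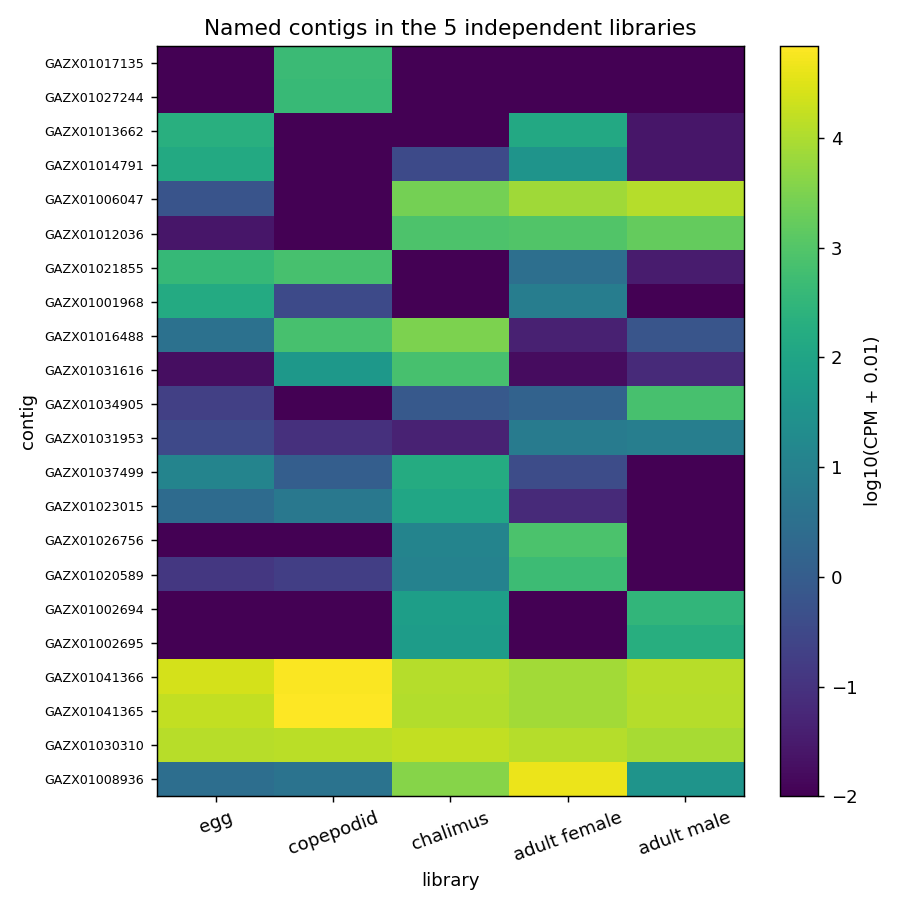
Level of each named contig (rows) in the 5 independent libraries (columns), coloured by log10(CPM + 0.01). GAZX01006047 and GAZX01012036 have 0 counts in copepodid and are abundant in chalimus and both sexes, and GAZX01016488 is abundant in chalimus and near 0 in the adults.

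Contigs with at least 80% of their scaled abundance in a single one of the 5 independent libraries were counted as concentrated there. Copepodid had 7232 such contigs, adult female 449, chalimus 437, egg 316 and adult male 197. They held 13.0% of the copepodid counts, 17.5% of the female, 4.16% of the chalimus, 3.34% of the male and 2.66% of the egg counts. Their median length was 322 nt in copepodid and 1405 nt in adult female. Adult female and adult male together held at least 80% of the abundance of 1051 contigs. With all 6 files, as planned, the numbers were 7158 for copepodid, 395 for chalimus, 242 for egg, 1 for adult male and 0 for adult female, because the file of unstated sex repeats the adult counts. The tau index of specificity over the 5 libraries had a median of 0.55 across 31420 contigs.

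The adult file of unstated sex lay between female and male for 99.9% of the 7271 sex-biased contigs, which follows from its being their data counted together. A least-squares mixture over them gave a female share of 57.5% on TMM-scaled values and 53.4% on total-scaled values, and females contributed 53.4% of the summed counts.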

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

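All tests in this part were chosen after the data were seen.

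Against chalimus, 528 contigs were at least 4-fold higher in adult female and at least 4-fold lower in adult male, and 179 went the opposite way. These numbers are singled out because the sexes moved in opposite directions under one contrast, and the difference was not tested, since each sex is 1 library.

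The copepodid FPKM values were scaled by a total of which 1.08% was not in the table's counts, a signal outside the counts analysed here, whereas that share was between 0.0342% and 0.149% in the other files.

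The copepodid library stood apart, with 6260 contigs of 50 or more counts found in no other library. Sequencing depth argues the wrong way, because copepodid was the shallowest library. With all libraries thinned to its total the number was 6305, against at most 32 for the next library. Thinning left the copepodid counts unchanged, so its number could only stay or rise and the thinned value adds no separate support. The contigs of copepodid alone account for part of the low rank correlation, which reached 0.73 at most without them, below the bound of 0.80 set for a full explanation; that bound was strict, as the other libraries correlate from 0.71 upward, and the 687 contigs with 0 counts in copepodid alone are a separate matter. Counts left out of the copepodid table may account for those zeros. Of its FPKM total 1.08% is absent, and the 687 hold between 0.391% and 1.04% of the counts in the other libraries. The criterion set was a share within that range, and 1.08% lies just above it, so the criterion was not met. Absent counts also need not leave such zeros. Chalimus lacked 0.0837% of its total with 0 such contigs. Egg lacked 0.149% with 3 such contigs, which held at most 0.00962% of another library. The 687 are only part of the zeros, since 3330 contigs higher in chalimus had 0 counts in copepodid. Outside the 687, GAZX01006047 alone held 1.20% of the male counts, though 0.265% in chalimus and 71 counts in egg. The nearness of the percentages thus does not show that the absent counts would cover all zeros. Absent transcripts would give the same zeros, and the absent counts cannot be assigned to contigs, so this stays open. Reads from another organism in the pool may account for the short contigs (median 296 nt, against 1425 nt for contigs of the same copepodid FPKM), but the length ranges overlap, with a 95th percentile of 555 nt against a 5th percentile of 386 nt, so the separation set as the criterion was not met. This stays open because louse transcripts assembled from 1 library alone could be short fragments too, and no sequence was examined. The match on copepodid FPKM sets aside rarity in copepodid, but not the lack of reads from other libraries. Transcripts peculiar to the copepodid stage also remain open, as untested.

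The adult file of unstated sex matches the female and male files. A further library sequenced independently is argued against by 43.5% of contigs holding exactly the sum, where a separate library would give 1.31%. The female and male reads counted again as one set need equal totals, and the difference was 0 counts. No biological explanation was tested.

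Contigs that mark adult female were also counted in chalimus, where the 1360 contigs low in egg held 2.56% of the counts against 0.389% in adult male. Carry-over of reads from the female library as the only source would give one ratio for all contigs. The ratio of chalimus to female counts was examined in 135 strongly female-biased contigs (at least 10000 female counts, male at most 1% of female). It ran from 1.67% to 15.4% (5th to 95th percentile), a 9.20-fold range where counting error spans 1.09-fold. That argues against carry-over as the only source. Carry-over added to expression in chalimus would vary too, so a small share of it stays open. Female animals in the chalimus pool may contribute, but no value here decides it: chalimus exceeded male for at least 91.3% of the female-biased contigs in either egg group, which choosing contigs for a low male level largely fixes. The label gives no sex for the pool, and expression in immature animals of either sex would look alike.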

How the results depend on the processing

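Of 271 recomputed values, each scored alone, 242 kept their side or stayed within 1.5 times (correlations within 0.05) and 29 moved. These values include log2 ratios of contigs named for being the most extreme, which could hardly change side. They also include settings that left a library unchanged, such as copepodid thinned to its own total. The share that stayed is therefore no measure of robustness. The larger side of a comparison turned in 7 of 60 recomputations. Female versus male turned to 4043 higher and 3313 lower with total counts, 4216 and 3199 without the most abundant contigs in the scaling, 3576 and 3553 with 3 added counts, and 3124 and 3016 with intervals beyond 4-fold. Chalimus versus copepodid turned to 11865 higher and 10611 lower with no count minimum, and to 6729 and 3036 without contigs of copepodid alone, where copepodid versus egg turned to 3278 and 5652. Apart from the contigs each setting adds or removes, the cause was not tested. The 3 comparisons with chalimus as the reference kept their larger side in all 30 recomputations. These are not separate checks, since all share 1 chalimus library and the third repeats the female and male counts. Some settings also left the values unchanged, such as female versus chalimus scaled without the file of unstated sex. With no count minimum, copepodid versus egg gave 9816 lower, female versus chalimus 7406 lower, male versus chalimus 1326 higher and 4930 lower, and the adult file of unstated sex 4566 lower; all 3 adult files gave 323 higher and 3088 lower. With at least 10 counts, 178 were higher in all 3 adult files, 685 were concentrated in chalimus and 1 in adult female; with intervals beyond 4-fold 51 were higher in all 3. At 90%, 64 were concentrated in egg and 234 in chalimus; without the file of unstated sex, 449 in adult female and 197 in adult male. Leaving out contigs of copepodid alone, where rho was 0.58 to 0.73, and chalimus versus egg, with 3925 higher and 2380 lower, were chosen after seeing the data. Copepodid correlations were 0.50 to 0.62 by Pearson and 0.53 to 0.71 with 50 counts in each library. The other independent libraries correlated among themselves at 0.72 to 0.89 and 0.69 to 0.88 in these settings. The female share was 53.4% with total counts. Depth limits what can be said of contigs under 50 counts, which enter the 4-fold comparisons only with the lower minimums. Such contigs also enter other values, among them the main rank correlations, which use a minimum of 10 counts.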

Other observations

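Beyond the shares given above, the sex-biased contigs differed in how their members were placed in the larvae. Of the 2268 female-biased contigs that eggs also held, 1173 were at least 4-fold lower in copepodid than in adult female, 775 were at least 4-fold lower in chalimus, and 249 were at least 4-fold higher in egg than in adult female. Of the 1360 low in egg, 1191 were at least 4-fold lower in copepodid and 1018 in chalimus. Of the 3643 male-biased contigs, 327 were at least 4-fold higher in copepodid than in adult male and 208 were higher in chalimus. Each number rests on 1 library per group and has no replicate check.

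Contigs with the largest ratio between chalimus and egg, a comparison chosen after the data were seen, differed in their adult course. GAZX01002896 (447 nt) had 0 counts in egg, 609 CPM in chalimus, 838 CPM in adult female and 1047 CPM in adult male. GAZX01002888 (353 nt) had 0 counts in egg and copepodid, 377 CPM in chalimus and 395 CPM in adult male, but 40 counts in adult female. On the lower side, GAZX01021855 had 371 CPM in egg and 0 counts in chalimus.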
